A study of Mus musculus with 12 samples.

How the data were processed

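The data are RNA-seq libraries of single mouse amnions at embryonic day 7.5, 6 from controls and 6 from Smad5 knockouts. Per the labels' protocols, cDNA was made from the lysate with oligo-dT primers by a method for single cells, amplified by 18 and then 12 cycles of PCR, and sequenced on the SOLiD platform, with coverage of up to 3 kb from the 3' end of transcripts. Stages ran from before the head fold to 3 somites. TopHat2 2.1.1, Bowtie 1.1.2.0 and featureCounts 1.5.3, with the builds GRCm38 and mm10, are named in the submitters' processing notes, without a role or order.

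The authors deposited a table of raw counts per Ensembl gene, with gene length and GC percent for each gene as deposited. A deposited sheet named as variance-stabilised values is on another scale: the deposited values behave as RPKM made from whole numbers after full-quantile normalization. All 192396 of them were whole numbers (within 0.01) once multiplied by gene length and divided by a constant, and all 16033 ranks held the same whole number in every library. The authors also deposited tables of their own comparisons, with a log2 fold change, its standard error and p-values per gene; the tool is not given in the sources used here, and the column names are those that DESeq2 writes. Of the 38561 gene IDs counted, 1513 have no name in the count table or in the reference table used here and kept their ID; they held 0.205 to 0.305% of counts. Coordinates are those in the count table, of which 36582 of the 36639 that could be compared (99.84%) overlapped the reference annotation of the same build. Whether counting used strand is not given in the sources used here, so overlapping and antisense genes are uncertain.

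Counts as deposited were tested with edgeR 4.0.16 (quasi-likelihood test with robust dispersion, TMM scaling, filterByExpr with a count minimum of 10 and a total of 15) in R 4.3.3, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The knockout comparison used all 12 libraries. SetA, SetB and the 5 controls without the outlier label shared 1 fit of 11 libraries. Values per library are CPM with TMM-scaled library sizes, and log2 fold changes are edgeR's. The ± after a gene's log2 fold change is a standard error derived from the test. It is the absolute log2 fold change divided by the square root of the test's F statistic. The common biological coefficient of variation was 0.555 in the fit of 12 libraries and 0.56 in the fit of 11. On simulated data for the knockout comparison, 13.8% of genes changed 2-fold, 62.3% of those changed 4-fold and 93.4% of those changed 8-fold were recovered among 11767 genes, with 2 unchanged genes called. For SetB against control the shares were 0%, 34.4% and 62.5% among 13033 genes, with 2 unchanged genes called. Changes of about 2-fold were thus mostly not recovered in the simulations. Far fewer genes were changed there than were called in the SetB data (1541), so the shares can understate recovery in the data. Depth was not varied. Counts come from PCR products without molecular identifiers.

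The 28 gene lists, the comparisons, the tests and the rule for naming genes were set before the data were examined. Lists with at least 5 tested members, other than the sex-linked check genes, were tested with camera in limma 3.58.1 on log2 CPM (prior count of 2) at an inter-gene correlation of 0.01, adjusted over the lists of each comparison. This called 14 of 23 lists for the knockouts, 12 of 26 for SetA, 11 of 26 for SetB and 10 of 26 for SetB against SetA. With a correlation estimated from the data, 0, 0, 1 and 1 of these calls held, the last 2 being trophoblast and chorion. Lists share members, and the list counts are calls over all genes unless said to be adjusted over the list alone. Median log2 fold changes of lists holding a gene with 0 counts in a group were also taken with that gene at a floor of 3 counts over the group, which moved the trophoblast and chorion median in SetA from -1.24 to -1.22 and the matrix median in SetB against SetA from -0.72 to -0.42, and left the others as they were. The floor covers counting error only.

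Genes were named by a fixed rule. It takes the 12 largest increases and 12 largest decreases of each comparison among called genes with a log2 CPM of at least 3 that changed the same way in every changed library (in at least 5 of 6 for the knockouts). It adds Smad5 and up to 4 members with the smallest p from each list that held a call, and leaves out provisional names and sex-linked genes from the first part. Id1, Id3 and Ascl2 for the knockouts, and Eomes and Tnc between the subgroups, fall outside the rule and were chosen after their values were seen.

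Litter pairs the samples: the labels give litter mates the same number, and the design text calls the knockouts littermates of the controls. Deviations from the group means correlated within litters at 0.016 to 0.204 (median 0.119), against a median of -0.01 between litters, and 3 of the 6 knockouts correlated best with their own litter mate. The main test had no litter term. In the fit of 11 libraries KO 6 has no litter mate, so the blocked SetA effect rests on 2 pairs and mixes blocking with the loss of a library. For the main results, the blocked value is given where it changes a call or moves a count by over 1.5 times.

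Alternatives were another scaling (RLE), no filter and a stricter filter on low counts, litter, sex or stage as a term, no robust dispersion, the outlier control kept or left out, each library left out in turn, DESeq2 1.42.0, limma voom with quality weights, and limma on the quantile-normalized sheet (pseudocount of 0.5). An offset for GC content and gene length (lowess span of 0.3), alone and with the block, stage as a term with the outlier control kept, and leaving out litter 6 were added after seeing the data. Other splits of the libraries were refitted, at most 100 per comparison.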

Results

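Polyadenylated RNA was sequenced from 12 single mouse amnions at embryonic day 7.5, the thin membrane that encloses the early embryo. Smad5, the gene knocked out in 6 of them, encodes a protein that carries bone morphogenetic protein (BMP) signals to the nucleus. Each of the 6 knockout (KO) amnions came from the same litter as 1 of the 6 controls, and litter mates carry the same number here. The labels further divide the knockouts into SetA (KO 1, KO 3 and KO 6, n = 3) and SetB (KO 2, KO 4 and KO 5, n = 3), and call Control 6 an outlier. These divisions were named after analysis of the same libraries, so p-values for them are not independent evidence that the subgroups exist. SetA held 2 male and 1 female embryo, SetB held 3 females, and the 6 controls held 4 males and 2 females. Total counts per library ran from 7.55 to 14.5 M in the controls (mean 10.3 ± 2.68, SD, n = 6) and from 5.11 to 12.3 M in the knockouts (8.27 ± 2.37, SD, n = 6). The difference of -2.04 M lay within the spread between libraries (2-sided exact permutation test, p = 0.197, or 0.42 adjusted over 4 library measures). No pair of libraries held identical counts among the 66 compared, and none came within sampling noise of another.

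Smad5 transcripts (chromosome 13, 56703010 to 56742377, GRCm38) were lower in every knockout than in any control. They averaged 43.7 ± 23.1 CPM (counts per M counts of the library, SD, n = 6) in the knockouts and 89.7 ± 13.2 CPM (SD, n = 6) in the controls, a log2 difference of -1.22 (2-sided exact permutation test, p = 0.00216, the smallest that 924 splits can give). These splits ignored the litter pairs. Only 32 splits part every litter, so a paired test could not give so small a p, and none was run. Levels within the knockouts were 62.4, 72.7 and 56.7 CPM in SetA (KO 1, KO 3 and KO 6) and 31, 19.7 and 19.7 CPM in SetB (KO 2, KO 4 and KO 5), against 74.5 CPM in the lowest control. In the fit across all genes the change of -1.04 ± 0.33 (SE) did not pass (adjusted p = 0.0861, lower in 6 of 6), but it did without KO 3 (0.0279), with DESeq2 (0.0301) and with limma voom (0.00322). The part of the gene that the allele lacks is not given in the sources used here, and reads near the 3' end can lie outside it, so these values do not check the genotype labels.

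**Figure D1:**
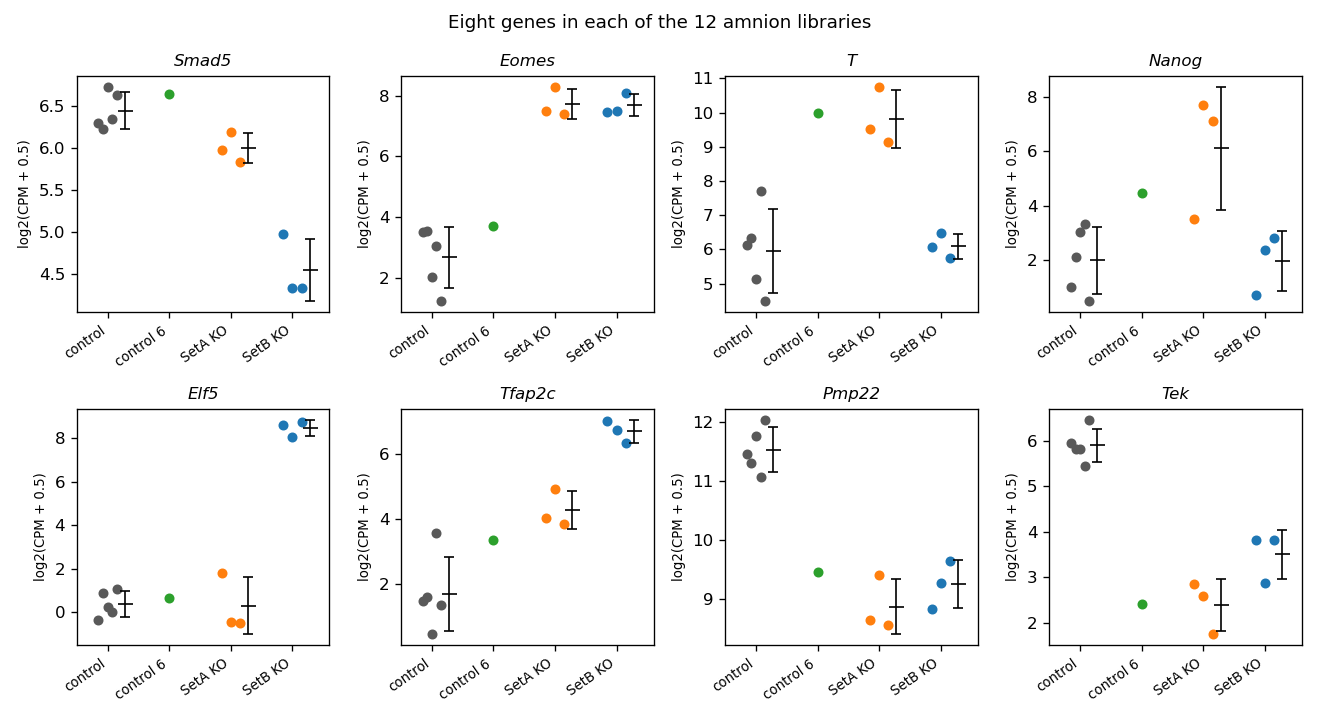
Each point is 1 library, on a log2(CPM + 0.5) axis, in the 5 controls, Control 6, SetA and SetB, and black bars give the mean ± SD of groups with more than 1 library. Eomes was at 167 to 314 CPM in the 6 knockouts and at 1.84 to 12.4 CPM in the 6 controls, while Elf5 was at 264 to 431 CPM in SetB and at 2.98 CPM or less in the other 9 libraries.

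The first comparison asks what loss of Smad5 changes in the amnion as a whole. Knockout amnions had more RNA of Eomes, a T-box factor of early mesoderm and trophoblast, and less RNA of genes of the extraembryonic mesoderm. Eomes (chromosome 9, 118478212 to 118486132) averaged 215 ± 62.1 CPM in the knockouts and 7.97 ± 4.39 CPM in the controls (SD, n = 6 each), a log2 fold change of 4.75 ± 0.43 (SE, adjusted p = 0.000119, higher in 6 of 6). Pmp22, a membrane protein gene (chromosome 11, 63128982 to 63159547), fell from 2640 ± 1200 to 555 ± 169 CPM (SD, n = 6 each; log2 fold change -2.25 ± 0.35, adjusted p = 0.012, lower in 6 of 6). Of 12076 genes tested, 467 passed the threshold, 163 higher and 304 lower.

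Of 16 extraembryonic mesoderm genes tested, 7 fell and none rose, and 11 fell when p was adjusted over the list alone. Besides Pmp22, they included Snai2 (log2 fold change -2.34 ± 0.43), a repressor of epithelial genes, Tbx20 (-1.8 ± 0.32) and Hand1 (-1.65 ± 0.34), both transcription factors of mesoderm. The list median was -1.64 (camera, adjusted p = 5.09e-08), and the adjusted p was 0.174 with an estimated correlation. BMP-SMAD target genes fell as a group as well, with 4 of 18 lower, 0 higher and a median of -0.93 (camera adjusted p = 1e-05, 0.155 with an estimated correlation). Adjusted over the list alone, 6 of them fell and 1 rose. Id4 (-2.51 ± 0.57), Nog (-2.48 ± 0.66), the gene of a secreted BMP antagonist, and Msx2 (-1.59 ± 0.31) were among the 4, while Id1 (-0.34 ± 0.26, adjusted p = 0.458) and Id3 (-0.63 ± 0.28, adjusted p = 0.207) did not pass.

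Genes of the contractile apparatus and stretch response fell in 2 of 13 cases, Tagln (-2.41 ± 0.54) and Tpm4 (-0.89 ± 0.21), and in 11 of 13 when adjusted over the list alone. Their camera adjusted p was 2.57e-06, or 0.174 with an estimated correlation. Basement membrane and matrix genes fell in 2 of 15 cases, Npnt (-2.11 ± 0.51) and Sparc (-0.93 ± 0.23), and in 12 when adjusted over the list alone (camera adjusted p = 2.02e-05, 0.174 with an estimated correlation). Lower camera calls were also made for cardiac muscle (1 of 13 lower, Gata6, adjusted p = 0.000551), the retinoic acid pathway (1 of 10 lower, Hoxa1, adjusted p = 0.00923), allantois (0 of 7, adjusted p = 0.0181), WNT response (0 of 14, adjusted p = 0.0284) and paraxial and lateral plate mesoderm (1 of 7 lower, Prrx2, adjusted p = 0.0375). With an estimated correlation these 5 had adjusted p = 0.174, 0.197, 0.197, 0.318 and 0.378.

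Trophoblast and chorion genes, markers of the neighbouring extraembryonic ectoderm, were higher in 5 of 10 cases and lower in 1, with a median of 3.62 (camera adjusted p = 0.0284, 0.353 with an estimated correlation). Besides Eomes, these were Elf5 (7.65 ± 1.58), Bmp8b (5.18 ± 1.36), Tfap2c (3.72 ± 0.73) and Ascl2 (3.53 ± 0.88), with Elf5 higher than the control mean in 4 of 6 knockouts. Bmp8b was at 100, 95.9 and 111 CPM in SetB but at 1.43, 0.234 and 0.107 CPM in SetA, and Ascl2 at 155, 111 and 124 against 2.46, 8.08 and 8.55 CPM. These rises, like that of Elf5, lay in SetB. The Bmp8b call was lost in 19 of 26 settings. The trophoblast and chorion list call ended without KO 2 (camera adjusted p = 0.0534), KO 4 (0.062) or KO 5 (0.0772), the 3 SetB libraries. Pluripotency and epiblast genes were higher in 3 of 13 cases, Utf1 (4.63 ± 1.13), Sox2 (3.11 ± 0.74) and L1td1 (2.54 ± 0.53), with camera adjusted p = 0.00841, or 0.174 with an estimated correlation. All 3 genes were called in SetB and none in SetA. The knockout calls of Utf1 and Sox2 were lost in 16 of 26 and 13 of 27 settings. Hypoxia and glycolysis genes rose in 3 of 15 cases, Ankrd37 (1.79 ± 0.46), Pdk1 (1.37 ± 0.27) and Pgk1 (1.33 ± 0.33). Their camera adjusted p was 0.0375, with 0.197 under an estimated correlation and 0.0627 with litter as a block. The cell cycle list had 1 of 20 members higher, Ccne1 (1.51 ± 0.26; camera adjusted p = 0.0181, 0.197 with an estimated correlation), and the p53 target list 0 of 12 (0.0293 and 0.322). Leaving out 1 library ended the calls for p53 targets (Controls 1, 2 and 5, KO 2, 3, 4 and 5, adjusted p up to 0.0772), hypoxia (Controls 2, 4, 5 and 6, KO 2, 3 and 4, up to 0.106), paraxial and lateral plate (Controls 1, 5 and 6, KO 2, 4, 5 and 6, up to 0.119), WNT (Controls 4 and 6, KO 2, 4 and 5, up to 0.0813), allantois (Controls 2, 3 and 5, up to 0.0817) and pluripotency (KO 3, 0.0501). With sex as a covariate trophoblast and chorion (0.139), p53 targets (0.119), hypoxia (0.114), paraxial and lateral plate (0.139) and WNT (0.106) lost theirs.

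The other 9 lists tested had no call. Amniotic and surface ectoderm genes were higher in 4 of 17 cases, Cldn6 (2.86 ± 0.65), Cldn7 (2.22 ± 0.4), Tfap2c and Epcam (1.18 ± 0.29), with a list median of -0.22, a mean of 0.4 and camera adjusted p = 0.529. Cell adhesion and tight junction genes split into 3 higher and 1 lower of 19 (adjusted p = 0.29, median -0.12, mean 0.43). Tek (-2.64 ± 0.54) and Flt1 (-1.22 ± 0.26), receptors of vascular growth factors, were the 2 of 9 endothelium genes that fell (adjusted p = 0.452). BMP ligands, receptors and SMADs had Bmp8b higher and Acvr1 (-1.54 ± 0.32) lower of 15 (adjusted p = 0.126, median -0.36, mean 0.04), primordial germ cell genes had 2 of 9 higher (0.288) and streak and nascent mesoderm genes 1 of 12 (0.26). The lists of NODAL signalling (0 of 10, adjusted p = 0.734), FGF-ERK response (0 of 11, 0.26) and immediate early and heat shock stress (0 of 10, 0.739) held no gene past the threshold. Primitive blood, neuroectoderm, visceral and definitive endoderm, and maternal blood and decidua had too few tested members, with Sox2 higher and Dab2 (-1.79 ± 0.27) and Cryab (-2.28 ± 0.49) lower among them.

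Outside the lists, the largest decreases were those of Tac2 (-4.33 ± 0.9), the neurokinin B gene, Nebl, Gpr50, Thbs1 (-3.59 ± 0.64), which encodes thrombospondin 1, Smoc2, Sdpr, Olfml2b, Tmem108, Cbln1, Emp1, Nexn and Rbms3 (-2.82 ± 0.53). Thbs1 went from 93.9 ± 77.2 to 7.75 ± 5.51 CPM (SD, n = 6 each). Under the naming rule, which asks for a rise in at least 5 of 6 knockouts, the largest increases included Eomes and Tfap2c of the lists. They were those of Trap1a (6.6 ± 1.37), Mt1, Lincenc1, Mt2, Fabp3, Tfcp2l1, Fabp3-ps1, Eomes, Apoc1, Syngr1, Upp1 and Tfap2c. Trap1a, Mt1, Mt2, Lincenc1, Tfcp2l1, Apoc1, Syngr1 and Fabp3-ps1 lay above the mean log2 CPM of the controls in 5 of 6 knockouts, but they and Fabp3 were high in the 3 SetB libraries only. Mt1 was at 138, 113 and 72 CPM in SetB, 1.94, 0.468 and 3.85 CPM in SetA and 0 to 1.88 CPM in the controls. None of these 9 genes passed in SetA (lowest adjusted p = 0.261, Tfcp2l1). The metallothionein genes Mt1 and Mt2, Fabp3 and its pseudogene Fabp3-ps1 are uncertain, because near-identical copies can share reads.

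The count rested on edgeR's quasi-likelihood test. With litter as a block it was 211, and 26 of the 57 named genes that passed still did, among them Eomes, Pmp22, Tbx20, Tek, Id4, Msx2, Thbs1, Tfap2c and Ccne1, while 31, among them Hand1, Snai2, Nog, Tagln, Elf5, Sox2 and Trap1a, did not (adjusted p from 0.0516 to 0.359). Leaving out 1 library moved the count to between 113 (without KO 4) and 1178 (without KO 3).

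The second comparison asks how SetA knockouts differ from the 5 controls without the outlier label. SetA amnions had more RNA of genes of the primitive streak and epiblast and less of extraembryonic mesoderm genes. T (brachyury), a marker of streak and nascent mesoderm (chromosome 17, 8434423 to 8442496), was at 1010 ± 632 CPM in SetA (SD, n = 3) and 82.9 ± 74.2 CPM in the controls (SD, n = 5), a log2 fold change of 3.6 ± 0.59 (SE, adjusted p = 0.00774, higher in 3 of 3). Tek, the angiopoietin receptor gene, fell from 60.7 ± 16.4 CPM (SD, n = 5) to 5.04 ± 1.97 CPM (SD, n = 3; -3.6 ± 0.44, adjusted p = 0.00255, lower in 3 of 3). Of 13438 genes tested, 356 passed, 138 higher and 218 lower, and Smad5 did not pass (-0.47 ± 0.27, adjusted p = 0.395). Control 6, which this fit leaves out, held 1020 CPM of T and 4.84 CPM of Tek, so it lay with SetA for both, and 12.4 CPM of Eomes, so it lay with the controls for that gene.

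Streak and nascent mesoderm genes rose in 8 of 15 cases and fell in none, and 12 rose when adjusted over the list alone (median 2.37, camera adjusted p = 1.95e-11, 0.0971 with an estimated correlation). They included Eomes (4.94 ± 0.5), Mesp1 (4.25 ± 0.9), Mixl1 (3.81 ± 0.8) and T. FGF-ERK response genes rose in 6 of 13 cases, among them the ligand genes Fgf5 (6.22 ± 0.99) and Fgf3 (1.44 ± 0.31), Spry4 (3.6 ± 0.75) and Etv5 (1.86 ± 0.27), with camera adjusted p = 4.3e-07, or 0.0971 with an estimated correlation. Pluripotency and epiblast genes rose in 4 of 14 cases, namely Fgf5, Nanog (4.65 ± 0.85), Tdgf1 (4.53 ± 1.05) and Pou5f1 (3.35 ± 0.8; camera adjusted p = 4.11e-06, 0.0971 with an estimated correlation). The germ cell list held 1 higher gene of 11, Nanog (camera adjusted p = 0.00785, 0.0971 with an estimated correlation). Neuroectoderm genes were higher in 1 of 7 cases, Gbx2 (3.64 ± 0.71; camera adjusted p = 0.0137), with 0.219 under an estimated correlation and 0.124 with litter as a block.

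Extraembryonic mesoderm genes fell in 9 of 17 cases, with a median of -1.66 (camera adjusted p = 1.71e-10, 0.0821 with an estimated correlation). Postn, the periostin gene, fell from 70.6 ± 51 CPM (SD, n = 5) to 1.6 ± 1.38 CPM (SD, n = 3; -5.47 ± 1.1, adjusted p = 0.0208), and Snai2 (-2.78 ± 0.48), Pmp22 (-2.65 ± 0.34), Tbx20 (-2.08 ± 0.42), Hand1 (-1.8 ± 0.43) and Igf2 (-1.8 ± 0.35) were also lower. Contractile genes fell in 2 of 14 cases (9 adjusted over the list alone; camera adjusted p = 4.26e-07, 0.0821 with an estimated correlation), and BMP-SMAD target genes in 1 of 18, Tbx20 (0.000614, 0.0971 with an estimated correlation). No matrix gene of 16 passed alone (camera adjusted p = 3.45e-05, 0.0971 with an estimated correlation). Lower camera calls with 1 of 9 allantois genes (Itga4, adjusted p = 0.0137), 0 of 13 cardiac genes (0.0216) and 1 of 11 retinoic acid genes (Dhrs3, 0.0316) had adjusted p = 0.173, 0.219 and 0.206 with an estimated correlation. With litter as a block, and so from KO 1 and KO 3 only, these 3 were lost, at 0.655, 0.133 and 0.506, and primitive blood was gained (median 2.14, adjusted p = 0.0173). Leaving out 1 library ended the calls for allantois (Controls 2 and 5, KO 6, up to 0.123), cardiac (Control 5, KO 6, up to 0.0626), retinoic acid (Controls 2 and 4, KO 6, up to 0.222) and neuroectoderm (Control 5, KO 3 and KO 6, up to 0.063).

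The remaining 14 lists had no call in SetA. Among them, trophoblast and chorion genes were higher in 1 of 14 cases, Eomes, and lower in 2, Wnt7b (-2.61 ± 0.58) and Hand1 (median -1.24, camera adjusted p = 0.301). Endothelium genes had Tek lower of 11, with a median of 1.35 (adjusted p = 0.434), and WNT response genes had Sp5 (2.19 ± 0.4) and Rspo3 (1.88 ± 0.37) higher of 14, with a median of 0.16 and a camera direction of lower (0.979). Genes of NODAL signalling (1 of 12 higher, adjusted p = 0.112), p53 targets (1 of 12 higher, Cdkn1a, 0.646), cell cycle (1 of 20 higher, Ccne1, 0.0991) and hypoxia and glycolysis (1 of 15 lower, Slc2a1 at -1.86 ± 0.41, 0.398) gave no call either. Visceral and definitive endoderm genes had 1 of 6 lower, Dab2 (-1.98 ± 0.34; adjusted p = 0.797), and both tested maternal blood and decidua genes, Wnt4 (-3.31 ± 0.47) and Cryab (-2.44 ± 0.45), were lower. Outside the lists, Zic3 (6.24 ± 1.1), Fst (5.85 ± 0.76), the follistatin gene, Sprr2a3, Apln, Sp8, Prss50 and Gna14 had the largest increases. Vnn1 (-6.38 ± 0.94), Cpeb2, Nebl, Elf4 (-5.26 ± 0.64), Synpo2l, Olfml2b, Tac2, Mtus2, Rnf144b, Wt1 (-4.36 ± 0.91) and Parm1 had the largest decreases. Sprr2a3 is uncertain, because close copies of it can share reads.

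Keeping Control 6 among the controls left 7 of the 356 calls by edgeR, with Eomes (4.77, adjusted p = 0.000561), Fgf5 (6.38, 0.0208) and Elf4 (-5.11, 0.00742) the only named genes still past the threshold. T went from 3.6 to 2.07 (adjusted p = 0.293), Fst from 5.85 to 2.28 (0.43) and Gbx2 from 3.64 to 0.78 (0.807), while Pmp22 (-2.45, 0.0514) and Tek (-3.36, 0.0658) kept most of their fold change. KO 6 has no litter mate in this fit, so a litter block leaves the pairs of KO 1 and KO 3. Then 67 genes passed, against 201 without KO 6 and without the block. With it, 14 of the 54 named genes that passed still did (Eomes, T, Mixl1, Pmp22, Snai2, Tek, Tbx20, Dab2, Vnn1, Cpeb2, Elf4, Wt1, Parm1 and Sprr2a3), while the other 40 had adjusted p from 0.0526 to 0.352.

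The third comparison asks the same of SetB. SetB amnions had more RNA of trophoblast and chorion genes and less of mesoderm, matrix and contractile genes. Elf5, a transcription factor of trophoblast stem cells (chromosome 2, 103411688 to 103450989), was at 363 ± 87.9 CPM (SD, n = 3) against 0.881 ± 0.565 CPM in the controls (SD, n = 5), a log2 fold change of 8.68 ± 0.7 (SE, adjusted p = 2.25e-05, higher in 3 of 3). Msx1, a BMP target, fell from 639 ± 108 CPM (SD, n = 5) to 109 ± 62.6 CPM (SD, n = 3; -2.55 ± 0.44, adjusted p = 0.00281, lower in 3 of 3). Of 13438 genes tested, 1541 passed, 660 higher and 881 lower, and Smad5 was among the lower ones (-1.91 ± 0.29, adjusted p = 0.0012).

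Trophoblast and chorion genes rose in 10 of 14 cases and fell in 1, with a median of 4.73 (camera adjusted p = 3.59e-08, 0.0059 with an estimated correlation). Beside Elf5, Esrrb (7.77 ± 0.9), an orphan nuclear receptor, Rhox6 (7.24 ± 0.79), Bmp8b (5.95 ± 0.71), Eomes (4.88 ± 0.49), Tfap2c (4.81 ± 0.64) and Wnt7b (4.64 ± 0.5) were higher. The p53 target list also had a higher call, with Perp (1.89 ± 0.3), Sesn2 (2.12 ± 0.63) and Btg2 (2.41 ± 0.59) higher of 12 (camera adjusted p = 0.000924, 0.0682 with an estimated correlation). Perp is also a gene of epithelial junctions.

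Extraembryonic mesoderm genes fell in 12 of 17 cases (median -2.26, camera adjusted p = 2.39e-08, 0.0541 with an estimated correlation), among them Twist1 (-2.78 ± 0.61), Msx1, Col1a2 (-2.32 ± 0.34) and Pmp22 (-2.29 ± 0.33). Basement membrane and matrix genes fell in 10 of 16 cases, with Npnt (-3.07 ± 0.56), Frem2 (-2.19 ± 0.36), Fn1 (-1.82 ± 0.32), the fibronectin gene, and Col4a2 (-1.59 ± 0.34) as examples (camera adjusted p = 2.03e-06, 0.0541 with an estimated correlation). Contractile genes fell in 7 of 14 cases, among them Tagln (-2.91 ± 0.61), Flna (-1.87 ± 0.29), Tpm1 (-1.87 ± 0.34) and Tpm4 (-1.11 ± 0.23; 1.08e-06, 0.0541 with an estimated correlation). Of 18 BMP-SMAD target genes, 7 fell and 2 rose. Msx1, Bambi (-2.19 ± 0.29) and Msx2 (-2.12 ± 0.38) were lower and Gata2 (3.07 ± 0.49) was higher, with camera adjusted p = 0.000245, or 0.072 with an estimated correlation. Cardiac muscle genes fell in 3 of 13 cases (Gata6, Hand2 and Gata4), retinoic acid genes in 3 of 11 (Crabp1, Dhrs3 and Hoxa1), WNT response genes in 3 of 14 (Wnt5a, Lef1 and Dkk1), allantois genes in 3 of 9 (Wnt5a, Hoxd9 and Hoxa10) and paraxial and lateral plate genes in 3 of 9 (Prrx2, Prrx1 and Twist1). Their camera adjusted p were 0.000245, 0.00135, 0.00183, 0.0019 and 0.003, and 0.072, 0.072, 0.0682, 0.072 and 0.072 with an estimated correlation.

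Lists without a call in SetB still held changed genes. Cell adhesion genes were higher in 7 of 20 cases and lower in 1, with the claudin genes Cldn4 (6.16 ± 0.92), Cldn6 (3.74 ± 0.62) and Cldn7 (2.48 ± 0.48) and the E-cadherin gene Cdh1 (2.08 ± 0.34) higher (camera adjusted p = 0.067). Amniotic and surface ectoderm genes were split, 5 higher and 2 lower of 17 (0.464). Pluripotency genes were higher in 5 of 14 cases, among them Utf1 (5.49 ± 0.69) and Sox2 (4.02 ± 0.62), with a median of -0.16, a mean of 0.81 and camera adjusted p = 0.206. Hypoxia and glycolysis genes were higher in 6 and lower in 2 of 15 (0.112), cell cycle genes 3 and 2 of 20 (0.0634), and BMP ligands, receptors and SMADs 1 and 5 of 15 (0.112), with Bmp8b higher and Smad1 (-1.38 ± 0.31) and Bmp4 (-1.14 ± 0.32) among the lower. Streak genes had only Eomes higher of 15 (median -0.96, adjusted p = 0.214). Primitive blood had 2 of 5 higher, Gata1 (5.63 ± 1.15) and Runx1 (2.65 ± 0.66; 0.0551), neuroectoderm 2 of 7 higher (0.0551), and endothelium 3 of 11 lower (0.0551). Litter as a block gave calls for the streak (lower, adjusted p = 0.0155), endothelium (lower, 0.0331) and neuroectoderm lists (higher, 0.0331).

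The largest increases in SetB were those of Triml2, Dppa4 (9.43 ± 0.85), Nr0b1, Elf5, Prss50, Tmem114, Ppp2r2c, Duox2, Esrrb, Rhox5, Cldn3 and Trap1a (7.46 ± 0.8). Triml2 was at 31.3 ± 12.2 CPM in SetB (SD, n = 3), against a single read over the 5 controls. The largest decreases were those of Gpr50 (-5.84 ± 0.94), Slit2, Gulp1, Tac2, Smoc2, Car3, Tmem108, Col4a5, Ifit2, Gas1, Thbs1 and Col9a1 (-3.86 ± 0.49). Genes of the Rhox family are uncertain, because they have close copies that can share reads. With litter as a block edgeR called 527 genes, and 69 of the 97 named genes kept their call, among them Elf5, Esrrb, Msx1, Fn1, Col1a2 and Smad5, while 28, among them Tagln, Tpm4, Smad1, Bmp4, Runx1, Sesn2 and Btg2, did not (adjusted p from 0.0533 to 0.161). The count was 637 without KO 2, 707 without KO 4 and 896 without KO 5.

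**Figure D2:**
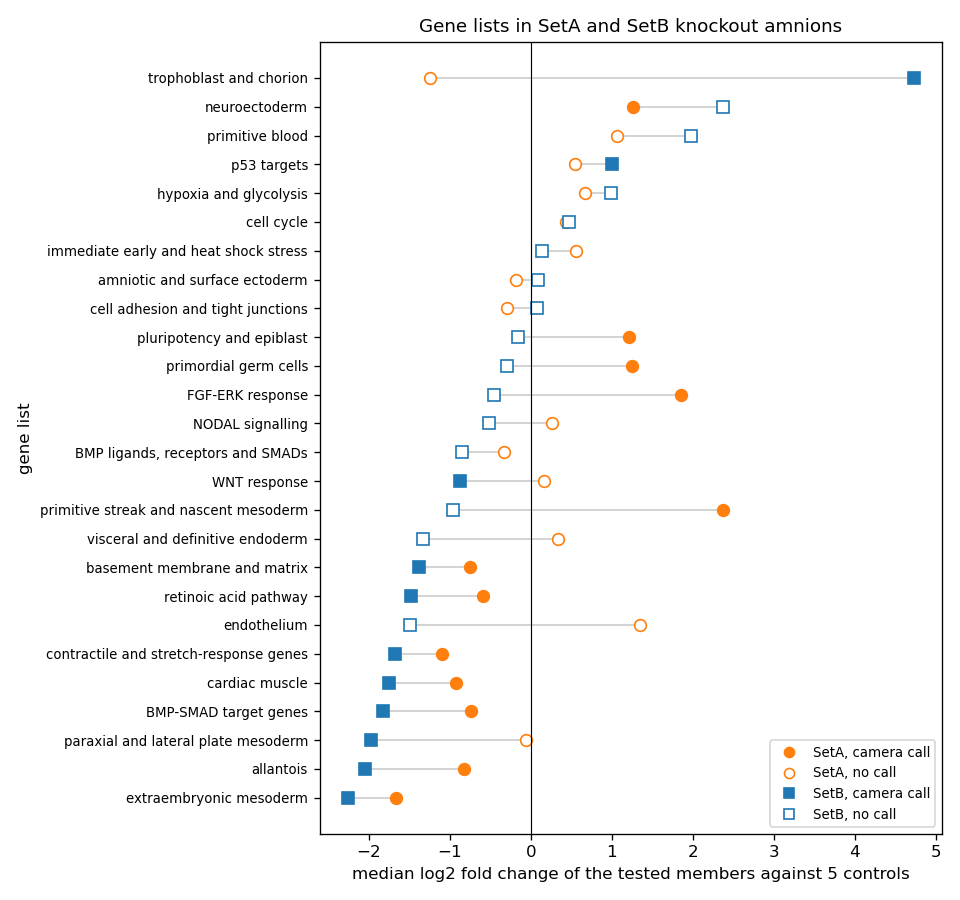
Each row is a gene list with at least 5 tested members, and the horizontal axis gives the median log2 fold change of its members against the 5 controls in SetA (circles) and SetB (squares), filled where camera made a call. Extraembryonic mesoderm lay at -1.66 in SetA and -2.26 in SetB, while streak genes lay at 2.37 and -0.96 and trophoblast and chorion genes at -1.24 and 4.73.

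The fourth comparison tests the difference between the knockout subgroups directly. SetB had more RNA of trophoblast and chorion genes than SetA, and less of streak and FGF-ERK response genes. Trophoblast and chorion genes were higher in SetB in 8 of 14 cases and lower in none (median 4.55, camera adjusted p = 8.51e-12, 0.00157 with an estimated correlation), among them Elf5 (8.35 ± 0.88, adjusted p = 0.000299), Bmp8b (7.47 ± 0.97) and Wnt7b (7.26 ± 0.71, adjusted p = 0.000269). Eomes did not pass, at 220 ± 81.7 CPM in SetA and 211 ± 53.9 CPM in SetB (SD, n = 3 each; log2 fold change -0.06 ± 0.52, adjusted p = 0.971). Of 13438 genes tested, 459 passed, 230 higher and 229 lower.

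Streak and nascent mesoderm genes were lower in SetB in 6 of 15 cases (13 adjusted over the list alone; median -3.37, camera adjusted p = 4.59e-12, 0.0723 with an estimated correlation), with Mesp1 (-5.86 ± 1.24), Mixl1 (-5.56 ± 1.08), T (-3.87 ± 0.73) and Evx1 (-3 ± 0.6) among them. FGF-ERK response genes were lower in 5 of 13 cases, among them Il17rd (-2.58 ± 0.49), Spred1 (-1.94 ± 0.45) and Fgf3 (-1.66 ± 0.37; 2.85e-06, 0.133 with an estimated correlation). Fgf5 was at 30.2 ± 18 CPM in SetA and 0.0757 ± 0.0732 CPM in SetB (SD, n = 3 each, adjusted p = 0.00777). WNT response genes were lower in 4 of 14 cases, among them Sp5 (-3.15 ± 0.5) and Lef1 (-2.3 ± 0.48), and paraxial and lateral plate genes in 2 of 9, Twist1 and Prrx1 (camera adjusted p = 0.00234 and 0.000273, both 0.0723 with an estimated correlation). Endothelium had no single gene past the threshold of 11, with a lower list call (median -2.38, adjusted p = 0.00927, 0.0723 with an estimated correlation). The adhesion list (2 of 20 higher, Cldn4 and Cdh1) and the p53 target list (1 of 12 higher, Perp at 3.05 ± 0.37) had higher calls, both at 0.00927, or 0.293 and 0.133 with an estimated correlation. Cardiac muscle (0 of 13, 0.0387) and matrix genes (2 of 16 lower, Fn1 and Frem2, 0.0489) had lower calls, with 0.293 and 0.298 under an estimated correlation. The matrix median of -0.72 was -0.42 with Tnc, at 0 counts in SetB, set at a floor of 3 counts over the group, and its call was lost with litter as a block (adjusted p = 0.315). The block gave calls for germ cells (0.0049), allantois (0.00535) and the retinoic acid pathway (0.00801), all lower in SetB. Leaving out 1 library ended the calls for matrix (Controls 2 and 3, KO 1, 2, 3 and 6, up to 0.136), cardiac (KO 1, 2, 3 and 6, up to 0.475), adhesion (KO 1, 0.196), p53 targets (KO 1, 0.122) and endothelium (KO 3, 0.0502). Sex as a covariate ended those for cardiac (0.14), matrix (0.113), adhesion (0.118) and p53 targets (0.0717).

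Beyond these, AU018091, Dnmt3l (8.48 ± 1.15), Sox21, Nr0b1, Rhox5, Tex19.1 and Esrrb had the largest increases, and Fst (-6.8 ± 1.01), Tdgf1, Sp8, Sprr2a3, Car3, Chrdl1, Apln, Nanog (-4.81 ± 1.07) and Gna14 the largest decreases. Triml2 had no read in SetA and 31.3 CPM in SetB, and Rhox6, Cldn3 and Duox2 had 1 to 3 reads over SetA. Smad5 was lower in SetB (-1.45 ± 0.3, adjusted p = 0.0187, lower in 3 of 3). With litter as a block edgeR called 11 genes, and of the 61 named genes Rhox5, Mixl1, Evx1 and Wnt7b kept their call, against adjusted p from 0.0578 to 0.818 for the other 57. No litter holds a SetA and a SetB embryo, so that fit rests on the controls of litters 1 to 5. KO 6, whose litter mate is left out, adds nothing to it (267 genes without KO 6 and without the block). Leaving out 1 library moved the unblocked count to between 114 (without KO 2) and 1004 (without KO 1).

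Some genes were called in the same direction in both subgroups. Against the controls, both had 63 genes higher and 130 lower, against 6.78 and 14.3 for independent lists, and 6 genes were called in opposite directions. Both subgroups were tested against the same controls, which adds shared calls without any effect. The lists are thus not independent, and 6.78 and 14.3 can be too low as a baseline. Blocking on litter, edgeR called 6 genes higher and 23 lower in both, and with Control 6 kept among the controls 2 and 2. The covariance of the log2 fold changes was 0.77, against 0.22 ± 0.012 in simulations of unchanged groups (SD, n = 20), so the difference, which estimates the shared effect, was 0.55 ± 0.29 (jackknife SE over libraries). The correlation across genes, which are not independent replicates, was 0.43, against 0.35 simulated. With the controls split into 3 and 2, a different part for each subgroup, the median over 20 splits was a covariance of 0.6, 7 genes higher in both and 32 lower in both. Each split called fewer SetA genes than the 138 higher and 218 lower of the full fit. The 6.78 and 14.3 for independent lists therefore do not apply to the splits. Of the genes named for both comparisons, Eomes, Ccne1, Cldn7, Etv5, Gbx2 and Prss50 were called higher in both subgroups. Pmp22, Tek, Dab2, Prrx2, Tagln, Cryab, Tpm4, Ahnak, Tac2 and Dhrs3 were called lower in both. The block ended the SetA calls of all of these but Eomes, Pmp22, Tek and Dab2 (adjusted p from 0.0526 for Cryab to 0.352 for Tpm4). It also ended the SetB calls of Tagln (0.108), Tpm4 (0.0678), Cldn7 (0.0533), Etv5 (0.113), Gbx2 (0.161) and Dhrs3 (0.0894). With Control 6 kept, the SetA calls of all these genes but Eomes ended (adjusted p from 0.0514 to 0.807), and that of Eomes stayed.

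The authors' deposited tables call 1204 genes for SetA, 2794 for SetB and 1413 for SetB against SetA. Of the genes that edgeR called and those tables also list, 355 of 356, 1533 of 1535 and 458 of 458 were called there in the same direction and 0 in the opposite direction. Log2 fold changes across genes correlated at 0.983, 0.986 and 0.983 with those in the authors' deposited tables.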

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

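The tests of chorion tissue, of dilution by chorion and of streak or epiblast tissue, and the fits with an offset for GC content and length or with stage and the outlier control together, were chosen only after the results they address had been seen. In this section, ± after a median of called members is not an error of the median itself. It is the standard error of the same comparison on the mean log2 CPM of those members.

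Trophoblast and chorion genes stood out in SetB: the SetB minus SetA median log2 fold change was 4.55, from a median of -1.24 in SetA and 4.73 in SetB (camera on the difference, adjusted p = 8.51e-12, 0.00157 with an estimated correlation). Sex of the embryos, since all 3 SetB embryos were female, is argued against as the whole cause. With sex as a term the 10 called members had a median of 5.1 ± 0.2 (SE), against 5.34 ± 0.16 without it, and 9 of them kept their call. These 10 were picked in a fit of the same libraries, which favours a high median. The list of all tested members, which was not picked so, had a camera adjusted p = 4.33e-06 with sex as a term. Chorion tissue carried over in the dissection is a candidate source, as 10 members rose in SetB and the more abundant ones, Elf5 (264 to 431 CPM), Bmp8b (95.9 to 111) and Wnt7b (136 to 307), were high in all 3 libraries, and Eomes (177 to 273) was as high in SetA (167 to 314) and does not bear on it. It cannot be told apart from expression by the amnion itself, because the same libraries hold both, 10 of the 14 tested members already had at least 1 CPM in the controls, and 5 of the 15 members belong to another list too. The knockout of Smad5 stays open as well, with no test that separates it from tissue carried over.

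Extraembryonic mesoderm genes were lower in the knockouts, where the 7 called members had a median of -1.76 ± 0.36 (SE). The 7 were picked in that fit, which favours a low value in it and in the other fits of these libraries. By their labels, litter mates were of the same stage except in litters 1 and 5, so stage hardly differed between the groups. A linear stage term could therefore move the difference between the groups little. It left -1.76 ± 0.37, with 6 of the 7 still called, though over all genes it took the knockout calls from 467 to 281. An offset for GC content and length left -1.79 ± 0.34, with 6 called, so that trend is not the whole cause. With litter as a block as well, 2 were called (-1.73 ± 0.35), against 4 with the block alone (-1.74 ± 0.38). Dilution by chorion is argued against for SetA only, where only Eomes of the trophoblast and chorion list was called higher over all genes. Adjusted over the list alone, 2 members rose and 2 fell there, with a list median of -1.24. All 17 tested extraembryonic mesoderm genes had a SetA median of -1.66, against controls without Control 6. The 7 had a median of -1.87 ± 0.29 there, but they were picked in a fit that includes SetA, which favours a low value. In SetB, where 10 trophoblast and chorion genes rose, dilution was not tested and stays open. Loss of Smad5 may underlie the decrease, as a hypothesis, and RNA from other cells of SetA embryos was not excluded. In Control 6, Pmp22, Col1a2 and Ahnak of this list were also low, so low levels were not found in knockouts alone.

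Primitive streak genes also went apart, with a SetB minus SetA median of -3.37 (2.37 in SetA, -0.96 in SetB; camera adjusted p = 4.59e-12, lost at 0.0723 with an estimated correlation). Stage as a linear term, with the early Control 6 kept among the controls, left the 8 members called in SetA at a median of 3.62 ± 0.73 (SE), against 4.03 ± 0.51 as reported. Only 1 kept its call, and keeping Control 6 without a stage term gave 2.87 ± 0.71 and also 1 call. The 8 were picked in a fit of the same SetA libraries, which favours a high value and weakens this test. T, which is among them, was at 732 CPM in KO 1 (2 somites) and 1730 CPM in KO 3. It was at 69, 34.8 and 209 CPM in Control 1, Control 3 and Control 4, of like stages. Stage is therefore argued against only as a linear trend, and within that limit. At the earliest stage, T was at 562 CPM in KO 6 and at 1020 CPM in its litter mate Control 6, and Eomes at 167 and 12.4 CPM. Streak or epiblast tissue of the embryo may have come with the SetA amnions, and as 4 epiblast genes rose with the streak genes this cannot be told apart from a change within the amnion, which the same libraries would show.

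Other called lists with both opposite medians and opposite camera directions in the subgroups were FGF-ERK response (SetB minus SetA median -2.12, from 1.86 and -0.46, adjusted p = 2.85e-06), endothelium (-2.38, from 1.35 and -1.49, 0.00927) and cell adhesion and tight junctions (0.51, from -0.29 and 0.08, 0.00927). With an estimated correlation all 3 calls ended (0.133, 0.0723 and 0.293), and at the preset correlation endothelium also ended without KO 3 (0.0502), and adhesion without KO 1 (0.196) or with sex as a term (0.118). Lists that did not meet both conditions also had calls between the subgroups. Among them were WNT response (medians 0.16 in SetA and -0.88 in SetB, camera adjusted p = 0.00234) and paraxial and lateral plate (-0.06 and -1.98, 0.000273).

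Chance splits of the libraries were counted for each comparison. For the knockouts, chance is argued against: 1 of 100 splits, the real one, gave as many as 467 genes, and the next highest gave 247. With litter as a block, 1 of the 32 splits that part every litter gave as many as the real 211, the next highest 1. For SetA and SetB against the controls, 1 of 56 splits each gave as many as the real one (356 and 1541, next highest 3 and 0). As the subgroups were formed on these same libraries, a low share there is what forming them would give, and it does not show that they would recur. For SetB against SetA, 10 splits are too few for a share under 0.05 (1 of 10, real 459, next highest 0).

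Of 340 groups of values tested, 23 held a library far from the rest of its group, and 15 of the 23 were in Control 6. A rate of 1 in 20 would give 17, but it does not hold for genes picked because their groups differ. Many were named from the fit without Control 6, which leaves that library free to lie apart. In Control 6, lower than the range of the other 5 controls were Pmp22 at 702 CPM (2150 to 4190), Tek at 4.84 (43.1 to 87.6), Smoc2 at 0.691 (59.8 to 332), Col1a2 at 18.9 (130 to 186), Cryab at 10 (74.6 to 151), Ahnak at 158 (531 to 920), Flna at 223 (472 to 617) and Olfml2b at 4.61 (12.4 to 20.3). Higher there were Fst at 161 CPM (0.23 to 4.97), Rspo3 at 84.7 (13.3 to 23.1), Bmp7 at 72.9 (29.4 to 39.9), Ccne1 at 76.1 (39.2 to 48.4), Dnmt3b at 426 (278 to 315), Prss50 at 1.04 (0 to 0.166) and Tmem114 at 1.5 (0 to 0.279). The most abundant 10 genes took 10.9% of counts in Control 5 (5.83 to 7.67% in the other controls), and Dppa4 (0.345 CPM) and Duox2 (0.575 CPM) were also high there. Fgf5 was at 1.66 CPM in Control 4, Frem2 at 269 CPM and Triml2 at 0.0697 CPM in Control 1, Id4 at 17.7 CPM in KO 3 (1.94 to 4.49 in the other knockouts) and Tagln at 1.31 CPM in KO 2 (3.4 to 5.44).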

How the results depend on the processing

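Settings with the GC content and length offset, with stage and the outlier control together, and without litter 6 were chosen after seeing the data, and the cause of the changes below was not tested unless stated. Counts are in the order knockouts, SetA, SetB, SetB against SetA, as reported 467, 356, 1541 and 459 genes. The replicate block for litter gave 211, 67, 527 and 11, with the offset 82, 75, 602 and 21. Block and sex together left edgeR 0, 0, 0 and 0 genes, with 1502, 1537, 1075 and 638 at an unadjusted p under 0.05; no other tool was run on that design, which leaves few residual degrees of freedom. DESeq2 gave 1281, 991, 2449 and 1168, and voom with quality weights 1917, 524, 3179 and 954. The quantile-normalized sheet gave 844 for SetB against SetA. Stage as a covariate gave 281 for the knockouts, and leaving out litter 6 gave 730. Keeping the outlier control gave 7 for SetA, or 15 with stage, all 7 and 15 among the 356. The other settings stayed within 1.5 times.

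With 1 library left out, the knockout count ran from 113 to 1178 (113 without KO 4, 120 without Control 1, 143 without Control 2, 149 without KO 2, 150 without Control 3, 177 without KO 5, 255 without Control 5, 307 without Control 4, 1178 without KO 3). SetA ran from 151 to 384 (151, 208, 184 and 221 without Controls 1, 2, 3 and 5, 225 without KO 2, 201 without KO 6). SetB ran from 637 to 2252 (637, 707 and 896 without KO 2, KO 4 and KO 5), and SetB against SetA from 114 to 1004 (1004, 114, 245, 162, 151 and 267 without KO 1 to KO 6).

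Lists called, as reported 14, 12, 11 and 10, were 0, 0, 1 and 1 with an estimated correlation. They were 9 for the knockouts and 6 for SetB against SetA with sex as a covariate, and 9 for the knockouts with the replicate block and sex. Without 1 library they ran from 9 to 15, 8 to 12, 11 to 14 and 6 to 11, the 9 without KO 4 and the 6 without KO 1. The block changed no list call other than those in the results. At the preset correlation, extraembryonic mesoderm kept its call in all 21, 20 and 20 settings for the knockouts, SetA and SetB, and streak in all 20 for SetA, but an estimated correlation ended these calls (adjusted p = 0.174, 0.0821, 0.0541 and 0.0971). Trophoblast and chorion kept its SetB call in all 20 and with an estimated correlation (0.0059). For the knockouts, hypoxia held in 8 of 21 settings at the preset correlation, paraxial and lateral plate in 9 of 20, p53 targets in 10 of 21, WNT in 12 of 21, trophoblast and chorion in 13 of 21 and allantois in 17 of 21. For SetA, allantois and retinoic acid held in 13 of 20, neuroectoderm in 13 of 19 and cardiac in 14 of 20, and for SetB against SetA matrix in 6 of 20, cardiac in 12 of 20, and adhesion and p53 targets in 17 of 20. The other calls held in all settings at the preset correlation but at most 1.

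Named genes kept their direction under the settings run, except Gbx2 in SetB, at -0.35 with the outlier control (adjusted p = 0.887). Over all settings, 496 of 1552, 458 of 1429, 292 of 2522 and 381 of 1585 gene values lost their call. The covariance difference ran from 0.34 with the outlier control to 0.78 without KO 3. Its jackknife SE of 0.29 is made from the values with 1 library left out. Those values lie within it of their mean by construction, so that is no check of them. Smad5 was lower in the knockouts in all 27 settings and passed in 3 of them, DESeq2 (adjusted p = 0.0301), voom (0.00322) and without KO 3 (0.0279).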

Other observations

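Genes on the X chromosome were over-represented among the genes changed in SetB, in both directions. Of 600 tested, 34 were higher (5.67%) and 35 lower (5.83%) in SetB than in SetA, against 1.52% of autosomal genes each way (2-sided Fisher's exact tests, p = 2.64e-09 and 1.48e-09 adjusted over 8 tests; genes are not independent). Against the controls, 43 were higher (7.17%, against 4.84% of autosomal genes, adjusted p = 0.0247) and 73 lower (12.2%, against 6.32%, 8.03e-07). For all knockouts, 5 of 513 were higher (0.975%, against 1.38%, adjusted p = 0.56) and 23 lower (4.48%, against 2.43%, 0.0171), and SetA showed no excess either way (adjusted p = 0.467 higher, 0.424 lower). These tests were not in the design and were added once the files were in use. Rhox5, Rhox6, Trap1a and Nr0b1 are among the X-linked genes higher in SetB. The median log2 fold change of X-linked genes was -0.27 in SetB against SetA and -0.21 against the controls. The 3 SetB embryos were all female by their labels.

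Xist, the RNA of the inactive X chromosome, and the Y-linked genes mostly followed the sex labels. Xist was at 22.2 and 40.3 CPM in the female controls and at 29.6, 15.6 and 14.6 CPM in the female KO 3, KO 2 and KO 5, with 0 to 0.921 CPM in 4 males. Among libraries labelled male, it was at 7.52 CPM in Control 4 and 5.13 CPM in KO 6, beside Eif2s3y at 15.4 and 119 CPM. It was at 4.54 CPM in the female KO 4, with Eif2s3y at 0.648 CPM.

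Mitochondrial genes took 1.01% of counts in KO 1 and 2.76 and 2.21% in the other SetA libraries, against 4 to 5.47% in SetB and 2.77 to 5.17% in the controls. The first 3 principal components held 28.2, 16.8 and 12.2% of the variance. On the first, the SetB libraries lay at 64.8 to 92.3, the SetA libraries KO 1, KO 3 and KO 6 at 50.3, -41 and -9.9, and the controls at -66.2 to -12.4. On the second, Control 6 lay at -31.4, beside SetA at -92.9 to -35.8 and apart from the other 5 controls at 12.5 to 40.8. Fold changes rose weakly with GC content and fell with gene length across genes, at Spearman 0.26 and -0.25 for the knockouts and 0.24 and -0.25 for SetB.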
